A study of Homo sapiens with 10 samples.

How the data were processed

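Bulk messenger RNA was sequenced from human alpha-beta T cells (ABT, 5 libraries) and gamma-delta T cells (GDT, 5 libraries) that had been activated and expanded from blood mononuclear cells of healthy donors, per the labels. The stimulus, the culture time and any sorting step are not given in the sources used here. Every column of the deposited table has the word Control in its name, and the names do not say what it was a control for. Per the labels' protocols, poly(A) RNA was enriched with oligo(dT) beads and libraries were made with the NEBNext Ultra II RNA kit. No strand marking was stated, so reads from a gene and from its antisense partner could not be told apart, and no antisense gene is named.

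The submitters' processing notes list bcl2fastq 2.20, kallisto 0.46.1, R 4.0.5, edgeR and the GRCh38 build, without their roles. The authors deposited 1 table of 37092 genes by 10 libraries. The deposited values are a linear signal, CPM (read counts scaled to library size) with a scaling factor between samples, as the name of the deposited table and its values show. Column totals ran from 858431 to 1097940, with a geometric mean of 999279, and since plain CPM cannot sum to more than its nominal total, the unit was handled as a normalised signal. They are written as CPM here. The kind of factor and the filter applied by the authors are not given in the sources used here, and 572 rows were at 0 in all 10 libraries.

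Low values in each column clustered at multiples of 1 step, the worth of 1 read. Within a tolerance of 0.1 of a step, 60.3% to 69.5% of these low values were whole multiples, too few to rebuild counts, so no count test was run. Column total divided by step gave 25900000 to 31800000 reads for donors 1 to 4 of both groups. It gave 84100000 for ABT replicate 5 and 87100000 for GDT replicate 5.

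Rows holding a date in place of a symbol (27 rows, 0.24% to 0.379% of total CPM) and 104 rows of genes on the Y chromosome, XIST and TSIX were removed, which left 36961 rows. Positions and gene types came from GENCODE release 29 on GRCh38, matched by current or older symbol, and 69.0% of rows found a match.

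The model without a donor term, its alternative with the donor number as a block and the lists were fixed before the data were examined; the reading of shared numbers as shared donors was not. Values were log2-transformed after adding a pseudocount of 1. A fold given here is on that log2(CPM + 1) scale and understates the change of low genes. Genes with at least 1 CPM in at least 5 of the 10 libraries were kept (15499 genes). ABT and GDT were compared with limma 3.58.1 in R 4.3.3 (a linear model with a mean-variance trend), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Differences are GDT minus ABT. All p-values here are two-sided. The T cell receptor genes that check the labels were compared with an exact permutation test over 252 arrangements, whose smallest p is 0.00794.

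Of 36 gene lists, 2 served as label checks, and the 31 others with at least 5 measured members were tested with camera in limma, a competitive test with a preset correlation between genes of 0.01. Each list was also tested with its correlation estimated from the data and with fry, which asks whether the genes of a list move one way on balance and compares them with no other genes.

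Named genes followed a rule. It took all label-check members; the 12 genes with the largest increase and the 12 with the largest decrease among those with adjusted p below 0.05, a mean of at least 5 CPM in the higher group and no overlap between groups; and from each list up to 4 passing members with the largest difference and up to 2 of the most abundant members that did not pass. Receptor and immunoglobulin segments, classical HLA genes, KIR genes, genes deleted in some people, clone-named genes and pseudogenes were left out of the top 24. The rule gave 117 genes, of which 114 are given; the others and 1 chosen afterwards are not reported here. CXCR6, TRAV10, TRBV25-1, FCER1G and the segments TRGV4, TRGV7 and TRGV8 were chosen after their values were seen, as were C1QA, CD14, CYBB and APOE.

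The labels number donors 1 to 5 in both groups, and a shared number was read as a shared donor; this reading was made after the number of calls with the block had been seen once, and it rests on the labels alone. As a check, deviations from the group means over 15321 genes (receptor segments, HLA, KIR and some deletion-prone genes left out) were correlated across genes. Same-numbered libraries had correlations from -0.037 to 0.507 with a median of 0.358, and 4 of 5 pairs lay above 0.1. Differently numbered libraries had a median of -0.127. Centring on the group means draws these values below 0 where same-numbered pairs lie above it, so they add no separate support. Shared handling of same-numbered libraries could give the same pattern, and both replicate 5 libraries stood apart in depth. The check therefore cannot tell a shared donor from shared handling. The main model had no donor term, and the fit with the donor number as a block is given where it changes a call or moves a count by more than 1.5 times.

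The model was tested on simulated data made from the 15499 genes with 200 changed. Without the block it recovered 44% of the genes changed by 1 on the log2 scale and 95% of those changed by 2, with 5 false calls among 144. With the block it recovered 61% and 98%, with 10 false calls among 169. In 20 simulated runs camera called the shifted list 20 times, and it called 3 of 400 random lists. The simulated genes varied independently of each other. These runs therefore do not show how often camera errs on lists whose genes move together, such as the interferon list (estimated correlation 0.857).

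Alternatives covered the pseudocount, the filter, 3 other scalings, the variance model, sample weights, an exact Wilcoxon test, the donor block and each library left out in turn. Leaving out both donor 5 libraries, using donors 1 to 3 only, a term for donors 1 to 3 against 4 and 5, and 2 further list tests with the block were added after seeing the data. An outlying library in a group of 5 was one whose gap to the nearest library exceeded 0.71 of the range (Dixon's ratio). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.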

Results

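Gene expression was measured by bulk RNA sequencing in 5 libraries of expanded human alpha-beta T cells (ABT) and 5 of expanded gamma-delta T cells (GDT). The 2 cell types carry different antigen receptors, an alpha and a beta chain in one and a gamma and a delta chain in the other. The depth estimated from the smallest step between values was 25900000 to 31800000 reads in 8 libraries. It was 84100000 in ABT replicate 5 and 87100000 in GDT replicate 5. The comparison asked how the transcriptomes of the 2 cell types differed. The stimulus, culture time and any sorting of each group are not given, so an effect of culture cannot be told apart from one of cell type. The limma p-values of the main model weigh a difference against the spread between donors within each group of 5. Those with the donor block weigh it against the spread of the differences within same-numbered pairs. Those of camera compare the genes of a list with all other tested genes.

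The receptor chains separated the groups as labelled. TRDC, the delta constant region (chromosome 14, 22462932 to 22465787, GRCh38), had 713 ± 125 CPM in GDT and 10.6 ± 3.51 in ABT (SD, n = 5 each; exact permutation p = 0.00794). TRDV2 had 272 ± 20.8 CPM in GDT and 2.35 ± 1.18 in ABT, and TRGV9 had 141 ± 14.5 and 3.88 ± 1.93. These V segments form the receptor of the main gamma-delta subset of human blood. TRDV3 rose from 0.246 ± 0.176 to 2.55 ± 0.794 CPM. TRDV1, the V segment of another subset, stood at 4.2 ± 1.72 CPM in GDT and 3.15 ± 1.43 in ABT and was not separated (exact permutation p = 0.317, n = 5 each). TRGC1 rose from 25.1 ± 13.4 to 542 ± 79.8 CPM and TRGC2 from 50.9 ± 19.1 to 161 ± 22.0, though reads from these near-identical constant regions may be split between them. TRAC, the alpha constant region (chromosome 14, 22547506 to 22552154), fell from 965 ± 316 CPM in ABT to 229 ± 68.2 in GDT. TRBC2 was at 632 ± 290 CPM in ABT and 308 ± 70.9 in GDT (exact permutation p = 0.00794, n = 5 each; limma adjusted p = 0.128 over all genes and 0.0462 with the donor block). TRBC1 was at 352 ± 84.9 and 281 ± 71.3 CPM (exact permutation p = 0.214, n = 5 each), and these 2 beta constant regions also share reads. Over the 10 receptor genes, the exact p of 0.00794, the smallest possible here, adjusted to 0.00992. 0 libraries went against their group's label in TRDC, TRDV2 or TRGV9.

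**Figure D1:**
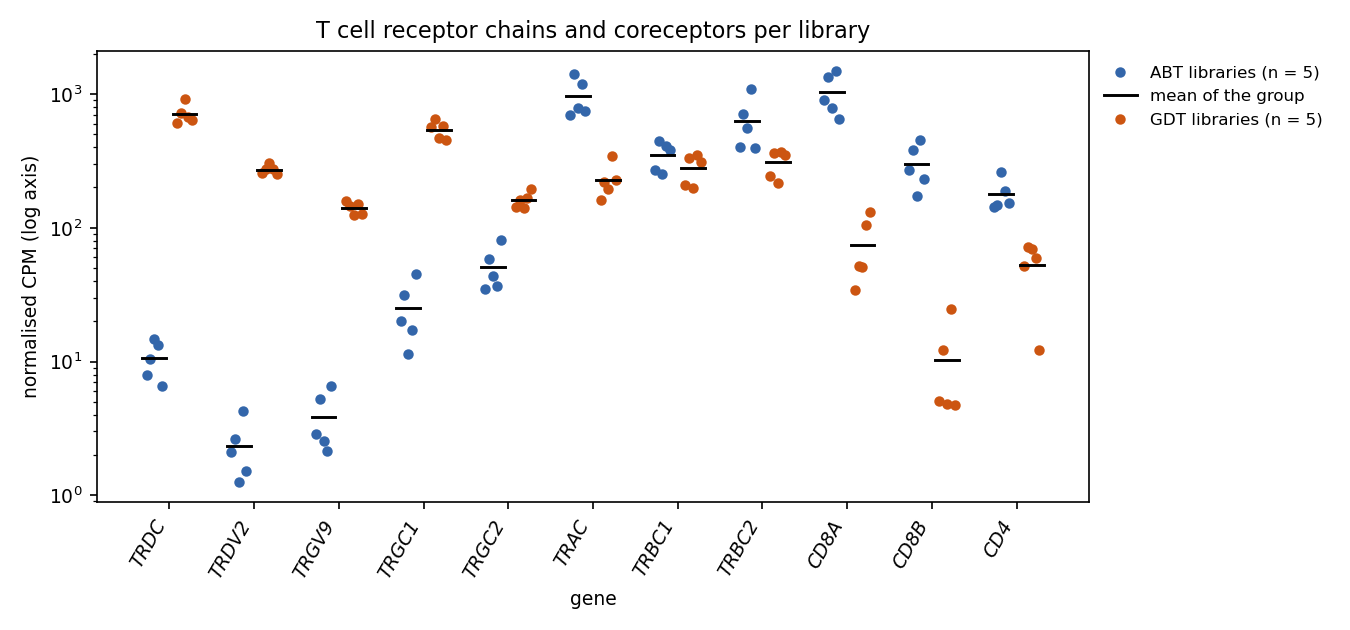
Normalised CPM (log axis) of receptor chain and coreceptor genes in each ABT and GDT library, 5 per group, with the group mean as a black line. TRDC lay at 608 CPM or more in the GDT libraries and at 14.8 CPM or less in the ABT libraries, while TRBC1 overlapped between groups.

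The coreceptors of conventional T cells were lower in GDT. CD8B fell from 300.5 ± 113 to 10.3 ± 8.71 CPM (log2 difference -4.94 ± 0.43 SE, limma adjusted p = 0.00013) and CD8A from 1035 ± 359 to 74.8 ± 41.7 CPM (-3.88 ± 0.36, adjusted p = 0.000257); both genes were lower in 5 of 5 donor pairs. CD4 fell from 178 ± 50.1 to 52.9 ± 24.1 CPM (adjusted p = 0.0354), a call lost in 7 of the 10 fits that left out 1 library (adjusted p up to 0.110, without ABT replicate 3). Of the 9 measured genes of the CD4 and CD8 lineage list these 3 fell and 6 did not pass. CD6 stood at 361 ± 85.0 CPM in ABT and 693 ± 256 in GDT (adjusted p = 0.118; 0.019 with the donor block). RUNX3, a transcription factor of CD8 and killer cells, was at 441 ± 72.8 and 582 ± 151 (adjusted p = 0.488). Adjusted over the list alone, 2 genes rose and 3 fell. The list's median was 0.16 while its mean was -0.88, and camera pointed down without passing (adjusted p = 0.306; 0.613 with an estimated correlation). By fry the list passed, downward (adjusted p = 0.0212; 0.00723 with the donor block). CD247, the zeta chain that signals for the receptor, rose from 176 ± 31.4 to 459 ± 109 CPM (1.36 ± 0.18, adjusted p = 0.00256). It was the 1 gene of 20 that passed in the list of the CD3 complex and receptor signalling, also adjusted over the list alone. CD3E stood at 604 ± 134 and 766 ± 118 CPM and ZAP70, a kinase of receptor signalling, at 589 ± 136 and 568 ± 135 (adjusted p = 0.432 and 0.947). That list as a whole was at the threshold (camera adjusted p = 0.0498; adjusted p = 0.613 with an estimated correlation). It did not pass with the donor block (0.0502), median-of-ratios factors (0.0517), quantile normalisation (0.292) or in 6 of 10 fits without 1 library.

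Across 15499 tested genes, 172 were higher and 204 lower in GDT by limma at the adjusted threshold, 139 and 174 of them by at least 2-fold. With the donor block, 334 were higher and 382 lower, and 357 genes were called in both fits. The calls held 15 receptor or immunoglobulin segments that were higher and 62 that were lower, and 135 and 123 protein-coding genes. Of the 376 called genes, 335 had no overlap between the groups; 707 of all tested genes (4.56%) had none, against 0.794% by chance. All 376 differences had the same sign in donors 1 to 3 as in donors 4 and 5, and 373 had it in 5 of 5 donor pairs. The called genes were picked from these same libraries, so their agreement in sign and lack of overlap were largely set by the picking. They are no independent support. Counts were lower without single libraries: 66 higher and 84 lower without ABT replicate 3, 75 and 88 without ABT replicate 2, 95 and 101 without ABT replicate 4, and 110 and 130 without ABT replicate 1. Those higher were 94 without GDT replicate 5 and 98 without GDT replicate 3. Without both donor 5 libraries 103 were higher and 88 lower.

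**Figure D2:**
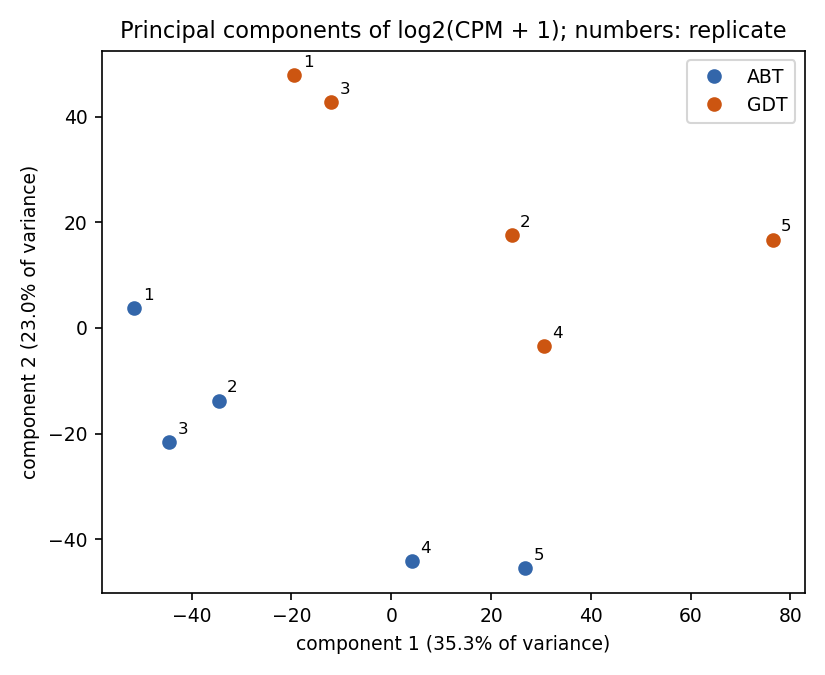
First and second principal components of log2(CPM + 1) over the tested genes, with 35.3% and 23% of the variance; points are libraries, coloured by group and numbered by replicate. ABT replicates 1 to 3 lay at or below -34.6 on the first component and ABT replicates 4 and 5 at 4.11 and 26.8, and GDT replicate 5 lay farthest to the right, at 76.5.

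The genes with the largest increases in GDT included cell-surface receptors and a transcription factor of innate-like lymphocytes. S1PR5, a sphingosine-1-phosphate receptor of killer lymphocytes, rose 14.9-fold, from 3.80 ± 5.05 to 54.6 ± 17 CPM (3.90 ± 0.47, limma adjusted p = 0.00126). ZBTB16, encoding the transcription factor PLZF of innate-like T cells, rose 13.3-fold, from 3.65 ± 1.30 to 64.0 ± 22.7 CPM (adjusted p = 0.000104). KLRB1, encoding the lectin receptor CD161, rose 13.4-fold, and KLRG1, another lectin receptor of effector cells, rose 10.1-fold. The 8 others, CD300A, AUTS2, PLCB1, RXRA, PLAU, C1orf21, CPNE5 and CRIM1, rose 5.29- to 7.37-fold (adjusted p from 0.000663 for PLCB1 to 0.0235 for CD300A). Among the largest decreases after CD8B and CD8A were LRRN3, a gene of naive T cells, at 169 ± 69.1 CPM in ABT and 18.3 ± 11.8 in GDT (10.2-fold lower, adjusted p = 0.00265), and ASIC1, an ion channel subunit, 9.29-fold lower. F5, SSTR3, TIMD4, ALPK1, LEF1, CDCP1 and AEBP1 were 5.32- to 7.29-fold lower (adjusted p from 0.0056 for F5 and AEBP1 to 0.0166 for SSTR3). In the fits without 1 library, the calls of CPNE5 (adjusted p = 0.0537 without ABT replicate 3), SSTR3 and LEF1 (0.0527 for both without ABT replicate 2) were each lost once. CD300A was lost in 7 of 10 fits (up to 0.0727, without ABT replicate 3).

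**Figure D3:**
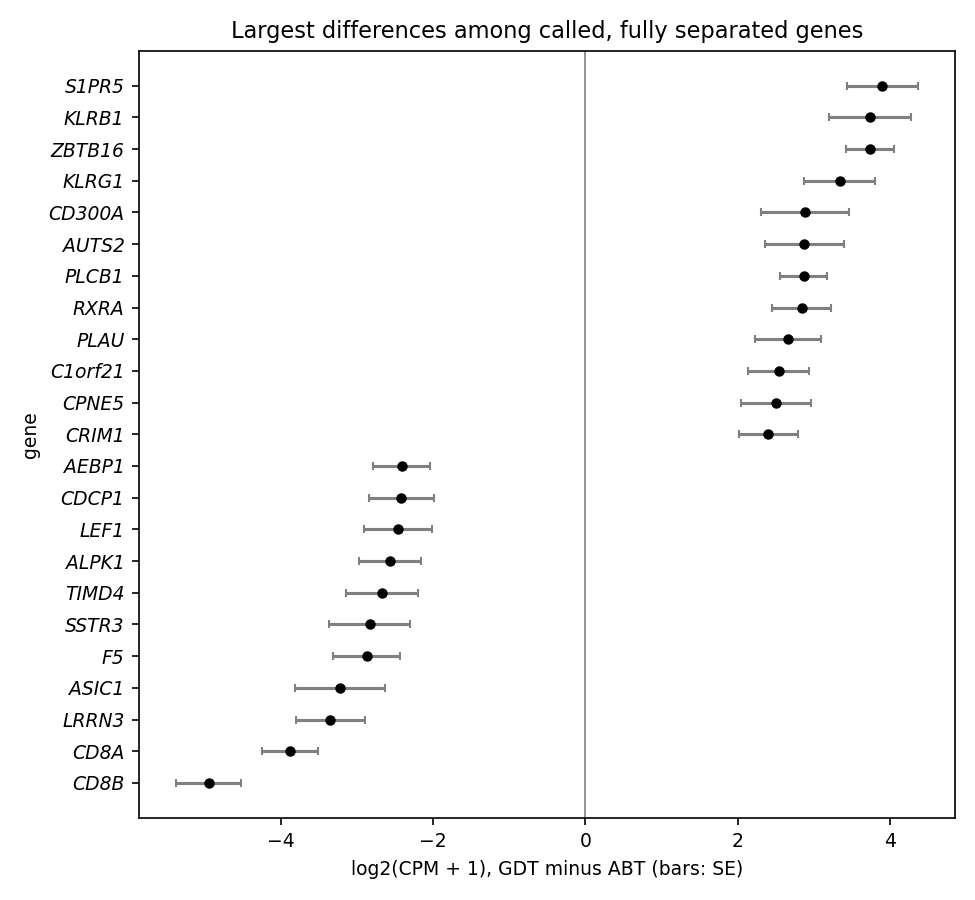
Log2(CPM + 1) difference, GDT minus ABT, with its SE, for the 12 genes with the largest increase and 11 of the 12 with the largest decrease among called genes whose groups did not overlap. The differences ran from -4.94 for CD8B to 3.90 for S1PR5.

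Some genes of killing were higher in GDT. Of 16 measured cytotoxic effectors, 3 rose, none fell and 13 did not pass (6 rose when adjusted over the list alone). NKG7, a granule protein, rose from 328 ± 86.6 to 946 ± 313 CPM (1.51 ± 0.27, limma adjusted p = 0.0127). CST7, a cathepsin inhibitor, rose from 157 ± 54.4 to 422 ± 85.9 (adjusted p = 0.00692), and FASLG, the Fas ligand, from 51.0 ± 4.97 to 108 ± 23.7 (adjusted p = 0.00796). GNLY and PRF1, encoding granulysin and perforin, were abundant in both groups, at 1301 ± 961 and 541 ± 81.3 CPM in ABT and 2481 ± 1496 and 937 ± 459 in GDT, and did not pass (adjusted p = 0.369 and 0.408). The list's median log2 difference was 0.59 (camera adjusted p = 6.38e-06; adjusted p = 0.184 with an estimated correlation; by fry 0.0181, and 0.121 with the donor block). The mean of the list (log2) was 8.13 to 8.39 in 4 GDT libraries, but 7.66 in GDT replicate 2, below the 7.70 of ABT replicate 5. Within same-numbered pairs GDT was higher each time, least in pair 2 (7.63 in ABT and 7.66 in GDT). GDT replicate 2 was also lowest of its group in the list of NK cell markers, at 3.01 against 4.15 to 4.76.

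Of 21 NK-type receptors and adaptors, 4 rose and 17 did not pass (9 rose adjusted over the list alone, and 6 rose with the donor block). KLRB1 rose from 17.9 ± 18.2 to 222 ± 161 CPM, KLRG1 from 7.35 ± 6.66 to 73.3 ± 27.1 and CD300A from 11.3 ± 6.33 to 103 ± 68.7. FCGR3A, the Fc receptor CD16, rose from 7.24 ± 10.2 to 95.7 ± 87.7 CPM (limma adjusted p = 0.0399), a call lost in 7 of 10 fits without 1 library (adjusted p up to 0.119, without ABT replicate 2) and with a pseudocount of 5. KLRK1, encoding NKG2D, was at 286 ± 126 and 357 ± 103 CPM, and SLAMF7 at 236 ± 64.4 and 291 ± 119 (adjusted p = 0.635 and 0.798). The list's median was 1.01 (camera adjusted p = 2.97e-07; adjusted p = 0.613 with an estimated correlation). The lists of NK cell and of macrophage markers were higher too by camera with the preset correlation, but did not pass by fry (adjusted p = 0.163 and 0.361). The mean of the macrophage list (log2) was 6.03 and 3.91 in GDT replicates 1 and 5. In GDT replicates 2 to 4 it was 1.20 to 3.02, within the 0.948 to 3.52 of ABT, and in pair 4 GDT was lower. The NK cell list shares NCAM1, NCR1, KLRC1, FCER1G and TYROBP with the NK-type list, so its rise is not a separate result. None of 8 NK cell markers and none of 9 monocyte and macrophage markers passed by limma over all genes (4 and 1 higher at an unadjusted p under 0.05; 4 and 0 rose adjusted over the list alone; with the donor block 3 NK markers rose). Their lists had medians of 1.27 and 1.22 (camera adjusted p = 0.0194 and 0.021; adjusted p = 0.613 for both with an estimated correlation). KLRC1, a receptor that shares reads with its paralogs, was at 26.8 ± 11.5 and 91.9 ± 43.5 CPM (adjusted p = 0.0746; 0.0155 with the donor block). CD7 was at 253 ± 91.2 and 187 ± 78.7 (adjusted p = 0.545). LYZ, encoding lysozyme of myeloid cells, ranged widely in both groups, at 28.3 ± 56.7 and 124 ± 201 CPM (adjusted p = 0.512). CD68 was at 18.9 ± 10.6 and 63.7 ± 93.1 (adjusted p = 0.607).

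Genes of naive and central memory T cells were lower in GDT. Of 17 measured, 5 fell, none rose and 12 did not pass (7 fell adjusted over the list alone, 8 with the donor block). LRRN3 fell as above. LEF1, a transcription factor, fell from 115 ± 43.2 to 23.6 ± 17 CPM (-2.45 ± 0.45, limma adjusted p = 0.0144). TCF7, another of memory T cells, fell from 234 ± 115 to 57.5 ± 42.3 CPM (adjusted p = 0.0374) and CCR7, a homing receptor, from 59.5 ± 14.4 to 15.5 ± 12.5 (adjusted p = 0.0235). The call of TCF7 was lost in 8 of 10 fits without 1 library (up to 0.0969, without ABT replicate 4) and under quantile normalisation, and that of CCR7 in 5 (up to 0.0751, without ABT replicate 3). TXNIP was at 262 ± 262 and 349 ± 144 CPM and SATB1 at 301 ± 72.2 and 227 ± 52.9 (adjusted p = 0.561 and 0.42). The list's median was -1.39 (camera adjusted p = 1.64e-08; adjusted p = 0.184 with an estimated correlation; by fry 0.0181, and 0.00294 with the donor block).

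**Figure D4:**
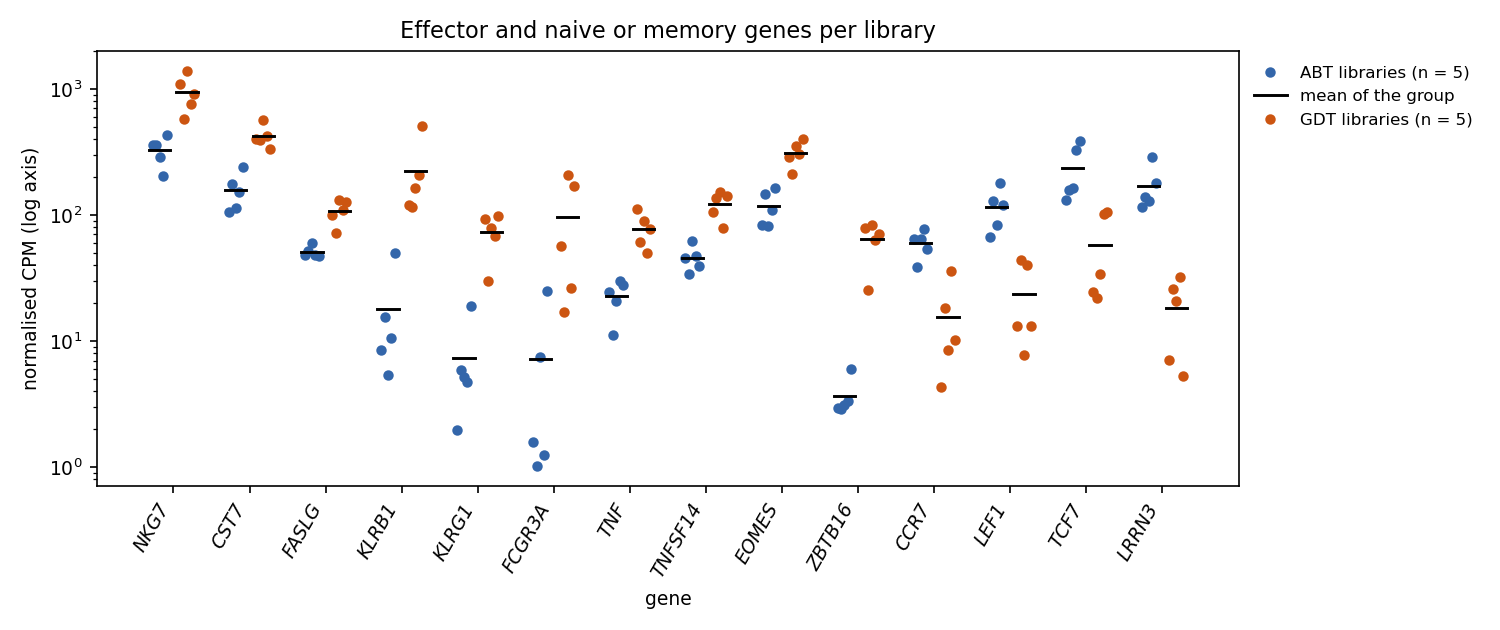
Normalised CPM (log axis) per library of genes of killing, NK-type receptors, cytokines, transcription factors and naive or memory T cells, 5 libraries per group, with the group mean as a black line. NKG7 had means of 328 CPM in ABT and 946 in GDT and LRRN3 means of 169 and 18.3; FCGR3A overlapped between groups.

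Cytokines and homing receptors differed gene by gene. Of 7 type 1 cytokines, TNF rose from 22.8 ± 7.32 to 77.8 ± 24.3 CPM (1.74 ± 0.28, limma adjusted p = 0.00744) and TNFSF14, encoding LIGHT, from 45.6 ± 10.7 to 123 ± 30.4 (adjusted p = 0.00547). The other 5 did not pass, nor did they adjusted over the list alone; LTB was at 440 ± 419 and 655 ± 286 CPM and LTA at 22.4 ± 17.8 and 50.3 ± 41.4 (adjusted p = 0.518 and 0.349). The list's camera adjusted p of 0.0456 was 0.22 with the donor block and 0.0517 with median-of-ratios factors. The adjusted p was 0.613 with an estimated correlation. Of 9 chemokines 1 rose (3 with the donor block, 1 adjusted over the list alone), CCL4, from 71.3 ± 40.9 to 284 ± 226 CPM (adjusted p = 0.0382). Its call was lost in 7 of 10 fits without 1 library (up to 0.114, without ABT replicate 2), and it shares reads with a near-identical copy. CCL5 stood at 1858 ± 1027 and 2743 ± 780 CPM and CCL3, which also has a near-identical copy, at 60.9 ± 38.2 and 226 ± 240 (adjusted p = 0.49 and 0.305). Of 25 chemokine and homing receptors, 4 rose, 2 fell (4 with the donor block) and 19 did not pass (7 rose and 6 fell adjusted over the list alone). Besides S1PR5 and CCR7 these included CCR6 and, outside the naming rule, CXCR6. CCR6 rose from 0.614 ± 0.903 to 7.33 ± 5.98 CPM (adjusted p = 0.0426). Its call was lost in 8 of 10 fits without 1 library (up to 0.13, without ABT replicate 3) and with a pseudocount of 5. CXCR6 rose from 94.7 ± 26.4 to 323 ± 146 CPM (adjusted p = 0.0139). The integrin chain ITGB7 was at 498 ± 39.4 and 523 ± 45 CPM and SELPLG, a selectin ligand, at 485 ± 113 and 544 ± 66.8 (adjusted p = 0.874 and 0.716). CCR6 was the 1 gene of 6 to pass among type 17 genes (2 adjusted over the list alone); RORA was at 173 ± 48.6 and 319 ± 102 CPM and AHR at 43.1 ± 9.07 and 38.4 ± 15.7 (adjusted p = 0.141 and 0.751). None of 7 type 2 genes passed by limma (3 lower at an unadjusted p under 0.05; 2 fell adjusted over the list alone and 2 with the donor block). CCR4 was at 100.5 ± 79.6 and 18.5 ± 17.6 CPM (adjusted p = 0.114; 0.0407 with the donor block). GATA3 was at 84.4 ± 19.1 and 74.0 ± 12.1 (adjusted p = 0.724).

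Of 22 effector and innate-like transcription factors, 2 rose, 1 fell (2 with the donor block) and 19 did not pass; 3 rose and 2 fell adjusted over the list alone. Beside ZBTB16 and TCF7, EOMES, a regulator of effector and memory killer cells, rose from 117 ± 36.5 to 311 ± 71.4 CPM (1.43 ± 0.23, limma adjusted p = 0.00796). BHLHE40 was at 460 ± 80.2 and 605 ± 251 CPM (adjusted p = 0.623). Of 23 cytokine receptors, 3 rose (4 with the donor block) and 20 did not pass (6 rose and 3 fell adjusted over the list alone). TGFBR3, a co-receptor for TGF-beta, rose from 30.3 ± 12.7 to 129 ± 45.0 CPM (adjusted p = 0.00744). IL18RAP, part of the interleukin-18 receptor, rose from 53.9 ± 26.4 to 156 ± 47.6 CPM (adjusted p = 0.0248) and TNFRSF1A, a TNF receptor, from 78.6 ± 17.1 to 148 ± 34.4 (adjusted p = 0.0328). The last pair lost their calls in 7 and 8 of 10 fits without 1 library (up to 0.0748 and 0.0896, both without ABT replicate 2) and under quantile normalisation. IL2RB and IL2RG, chains of the interleukin-2 receptor, stood at 1061 ± 188 and 642 ± 107 CPM in ABT and 1342 ± 262 and 906 ± 293 in GDT (adjusted p = 0.509 and 0.465). Among 24 immediate early and heat shock genes only FOSL2, an AP-1 factor, passed, also adjusted over the list alone (2 others fell with the donor block); it rose from 75.7 ± 6.54 to 166 ± 49.4 CPM (adjusted p = 0.0137; 0.052 without ABT replicate 3). The heat shock genes HSPA8 and HSP90AA1 were at 927 ± 353 and 668 ± 286 CPM in ABT and 801 ± 290 and 561 ± 219 in GDT (adjusted p = 0.816 and 0.827). Among 9 B and plasma cell markers BLK, a Src-family kinase, rose from 4.45 ± 1.37 to 22.3 ± 7.11 CPM (adjusted p = 0.00203), and 1 rose and 2 fell adjusted over the list alone. MZB1 was at 26.5 ± 9.52 and 10.5 ± 6.32 CPM (adjusted p = 0.0702; 0.0128 with the donor block). JCHAIN was at 7.35 ± 7.57 and 19.8 ± 12.7 (adjusted p = 0.33). Of 9 genes that mark MAIT and NKT cells, KLRB1, ZBTB16 and CCR6 rose, while TRAV1-2, a V segment of MAIT receptors, fell from 8.55 ± 2.88 to 1.43 ± 1.72 CPM (adjusted p = 0.0127). TRAV10 and TRBV25-1, segments of NKT receptors named outside the rule, fell from 3.53 ± 1.98 to 0.196 ± 0.123 and from 2.5 ± 1.07 to 0.182 ± 0.152 (adjusted p = 0.00227 and 0.00391). Falls of alpha and beta V segments follow from the cell types compared: 34 of 36 measured TRAV and 26 of 33 TRBV segments fell. These falls therefore say nothing about the share of MAIT or NKT cells. In the MAIT and NKT list 4 rose and 3 fell adjusted over the list alone (4 rose with the donor block). DPP4 was at 384 ± 129 and 449.8 ± 216 CPM (adjusted p = 0.919).

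Interferon response genes were lower in GDT as a list but not one by one. None of 29 passed by limma over all genes or adjusted over the list alone, 18 were lower at an unadjusted p under 0.05, and 7 fell with the donor block. Of the 29 differences, 28 were negative, with a median of -1.31 (camera adjusted p = 2.52e-09; adjusted p = 0.613 with an estimated correlation of 0.857). The mean of the list (log2) was 6.003 in ABT replicate 5 against 7.60 to 8.41 in the other ABT libraries, below GDT replicates 3 and 4 (7.15 and 7.43) and near GDT replicate 5 (5.78). Within same-numbered pairs GDT was lower each time, least in pair 5. OAS3, an antiviral enzyme, was at 1118 ± 538 CPM in ABT and 482 ± 374 in GDT (adjusted p = 0.362). None of 30 cell cycle genes passed, and 0 had an unadjusted p under 0.05; MKI67 was at 1241 ± 537 and 1185 ± 741 CPM and TOP2A at 477 ± 209 and 364 ± 221 (adjusted p = 0.907 and 0.699). The list had a median of -0.48 (camera adjusted p = 0.0232; adjusted p = 0.724 with an estimated correlation). None of 11 regulatory T cell genes passed (1 higher and 6 lower at an unadjusted p under 0.05; 1 rose and 5 fell adjusted over the list alone, and 1 fell with the donor block). IL2RA was at 193 ± 138 and 102 ± 80 CPM and TIGIT at 45.7 ± 22.7 and 59.0 ± 46.2 (adjusted p = 0.476 and 0.901). The list median was -1.09 (camera adjusted p = 0.021; adjusted p = 0.613 with an estimated correlation). Genes of oxidative phosphorylation (median -0.19, camera adjusted p = 0.0456) and cytosolic ribosomal proteins (median -0.19, 0.0194) were slightly lower as lists with none of 31 and none of 32 passing (1 and 2 lower at an unadjusted p under 0.05; with the donor block 1 gene of oxidative phosphorylation fell). Their adjusted p was 0.724 and 0.684 with an estimated correlation, and that of oxidative phosphorylation 0.0517 with median-of-ratios factors. ATP5B and ATP5A1 were at 438 ± 168 and 356 ± 145 CPM in ABT and 348 ± 114 and 255 ± 62.3 in GDT (adjusted p = 0.71 and 0.588). RPS2 and RPL3 were at 1204 ± 396 and 842 ± 184 CPM in ABT and 879 ± 229 and 812 ± 263 in GDT (adjusted p = 0.534 and 0.922).

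Of 31 lists tested, 12 passed with the preset correlation, 6 higher and 6 lower in GDT, and 0 with an estimated correlation. The 6 higher lists include the NK-type receptor and NK cell lists, which share members. Without 1 library the calls of the cytotoxic, NK-type receptor, naive and memory, and interferon lists held in 10 of 10 fits. Those of the type 1 cytokine, cell cycle and oxidative phosphorylation lists were each lost in 5, the macrophage list in 4, the ribosomal list in 3, the regulatory list in 2 and the NK cell list in 1. Among the 18 inhibitory receptor and exhaustion genes and the 15 costimulatory receptors none passed over all genes or adjusted over the list alone (3 higher and 2 lower, and 3 higher and 5 lower, at an unadjusted p under 0.05), and the list tests gave adjusted p = 0.935 and 0.465. LAG3 was at 884 ± 174 and 786 ± 586 CPM, CD96 at 440 ± 70.6 and 557 ± 199 and CD2 at 545 ± 82.5 and 677 ± 170 (limma adjusted p = 0.688, 0.652 and 0.628). TNFRSF1B was at 389 ± 94.1 and 457 ± 196 CPM (adjusted p = 0.891). None of 23 glycolysis genes passed (3 fell with the donor block, 2 adjusted over the list alone). GAPDH was at 2823 ± 1575 and 2035 ± 895 CPM and PKM at 1626 ± 951 and 1323 ± 551 (adjusted p = 0.805 and 0.912). Camera gave an adjusted p of 0.0747, or 0.00644 with the block and 0.0124 under quantile normalisation. For fatty acid metabolism none of 20 passed (1 fell with the block). FASN was at 526 ± 372 and 373 ± 234 CPM and SCD at 428 ± 389 and 357 ± 400.2 (adjusted p = 0.751 and 0.818), and camera gave 0.0587, or 0.032 with the block and 0.0126 under quantile normalisation. For amino acid transport and the ATF4 response none of 22 passed (1 fell with the block). The transporters SLC7A5 and SLC38A1 were at 417 ± 299 and 525 ± 85.4 CPM in ABT and 847 ± 372 and 484 ± 72.8 in GDT (adjusted p = 0.198 and 0.818). Camera gave 0.0747, or 0.0352 under quantile normalisation. No gene passed in the lists of MHC class II presentation, sterol synthesis, hypoxia or mitochondrially encoded transcripts (1 hypoxia gene rose over the list alone and with the block), whose camera adjusted p ranged from 0.364 to 0.743. CD74 and HLA-DRA of class II presentation were at 2345 ± 937 and 275 ± 92.9 CPM in ABT and 3042 ± 1620 and 275 ± 147 in GDT. SREBF2 and INSIG1, regulators of sterol synthesis, were at 306 ± 120.4 and 193 ± 153 in ABT and 349.6 ± 140.3 and 156 ± 127 in GDT. ERO1A and SLC2A1 of the hypoxia list were at 204 ± 49.0 and 87.9 ± 17.7 CPM in ABT and 154 ± 58.2 and 102 ± 13.1 in GDT. MT-CO1 and MT-ND4 were at 14103 ± 3863 and 7630 ± 2331 in ABT and 14017 ± 2529 and 6298 ± 1196 in GDT. Adjusted p for these 8 genes ran from 0.496 for ERO1A to 0.983 for MT-CO1. For the type 2, type 17, chemokine, homing receptor, transcription factor, cytokine receptor, immediate early, B cell and MAIT lists, camera gave adjusted p from 0.0716 for type 2 genes to 0.743.

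**Figure D5:**
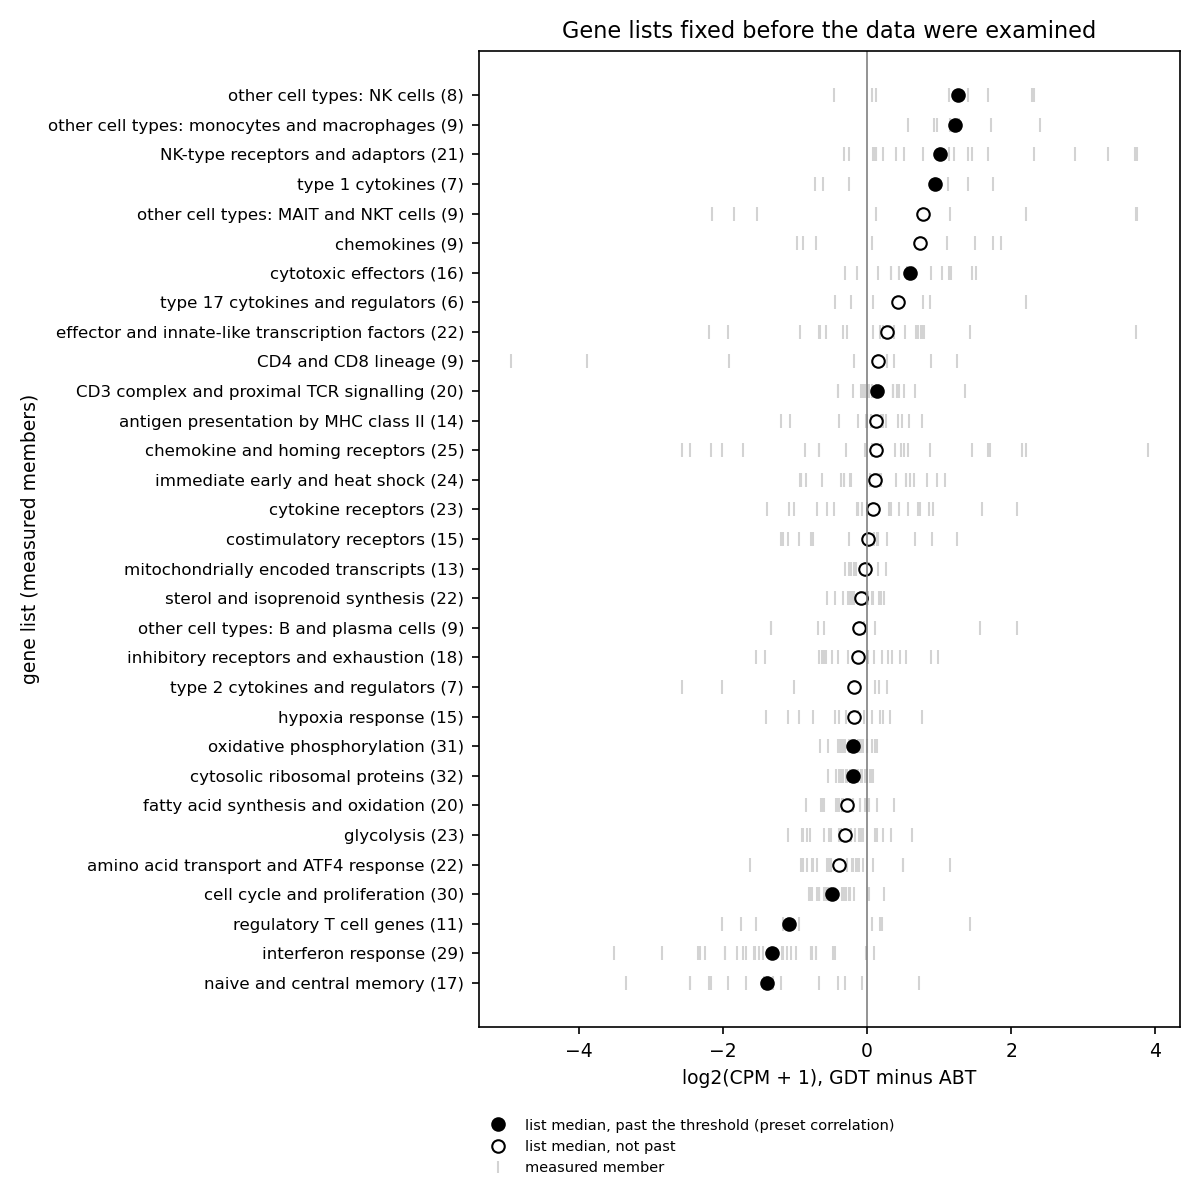
Log2(CPM + 1) difference, GDT minus ABT, of each measured member (grey ticks) and the median (circles) of 31 gene lists; filled circles passed camera with the preset correlation. The medians ran from -1.39 for naive and central memory genes to 1.27 for NK cell markers.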

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

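The tests on the T cell receptor and NK-type patterns, and those on the depth of replicate 4, were chosen only after the results had been seen; the tests on other splits of the libraries, the depth of donor 5, GC content and transcript length were set before. Dixon's ratio was computed for 250 group values, and 17 had a library far from the other 4 of its group, against 12.5 by chance at about 1 in 20.

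Depth stood apart in replicate 5 of both groups, at 84100000 reads in ABT against 26800000 to 29700000 in the others (ratio 0.949) and at 87100000 in GDT against 25900000 to 31800000 (0.904). ABT replicate 5 had the highest S1PR5, at 12.8 CPM against 1.34 to 1.73 (0.912), the highest ZBTB16, at 5.96 against 2.88 to 3.37 CPM (0.799), the highest TRGV7, at 6.13 against 1.79 to 2.38 CPM (0.797), and the lowest OAS3, at 242 against 1105 to 1683 CPM (0.783). ABT replicate 4 had the lowest MT-CO1, at 7286 against 15065 to 16516 CPM (0.888), and the lowest MT-ND4, at 3626 against 7519 to 9118 CPM (0.791), and ABT replicate 1 the highest AHR, at 58.9 against 36.5 to 41.3 CPM (0.742). In GDT, replicate 5 had the highest PLCB1, at 23.4 against 11.8 to 12.9 CPM (0.874), and the lowest CD4, at 12.2 against 51.9 to 72.3 CPM (0.809). Replicate 3 had the highest CCL4 in both groups, at 144 against 47.4 to 58.6 CPM in ABT (0.810) and 687 against 164 to 217 CPM in GDT (0.804). GDT replicate 2 had the lowest ZBTB16, at 25.4 against 63.5 to 82.5 CPM (0.775), and the highest SELPLG, at 660.1 against 494 to 531 CPM (0.754). GDT replicate 4 had the highest SSTR3, at 7.33 against 0.199 to 1.01 CPM (0.733), and GDT replicate 1 the lowest CD2, at 381 against 709 to 814 CPM (0.819).

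Alpha and beta chain transcripts were present in GDT: TRAC stood at 23.7% ± 7.07 of the ABT mean and TRBC1 plus TRBC2 at 59.8% ± 14.4 (SD, n = 5), against 10.4% ± 7.13 for the sum of 88 TRAV and TRBV segments, 7.23% ± 4.03 for CD8A and 29.6% ± 13.5 for CD4. The ratio of the V segment share to the TRAC share was 0.415 ± 0.215 and to the TRBC share 0.165 ± 0.0844, below 1 in 5 of 5 libraries for both, which argues against carried-over alpha-beta cells as the whole source. The bound of 1, less 2 SD, replaced a stricter one after the values had been seen: a ratio below 0.5 in 5 of 5 libraries, which TRBC met and TRAC met in 3 of 5, so the case against carry-over is weaker for TRAC, and carried-over cells as part of the source stay open. How reads divide between TRBC1 and TRBC2 does not change their sum. A candidate explanation is transcription of constant regions without a rearranged V segment in gamma-delta cells, a hypothesis that no test here addressed. The sums over J segments, given under other observations, bear on it but were not set against a prediction.

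Of 21 NK-type receptors and adaptors 4 rose in GDT, and the list passed camera with the preset correlation but not with an estimated one (adjusted p = 0.613) or by fry (0.126). Macrophage transcripts stood high in some libraries: LYZ, C1QA, CYBB and APOE were at 479.5, 53.8, 146.5 and 249.7 CPM in GDT replicate 1, and LYZ at 129.6 CPM in ABT replicate 4. In the 2 GDT libraries with LYZ, CD14, C1QA and CYBB no higher than the highest ABT library, the list's median difference from ABT was 0.50, against 1.01 in all 5. These 2 disagreed: the median difference was 0.974 in replicate 3 and -0.0657 in replicate 2. The list's mean (log2) in GDT replicate 2 was 4.37, above the 4.06 of ABT replicate 2 and below the 5.01 of ABT replicate 5. The mean of the NK-type list (log2) was 5.67 in GDT replicate 3 and 5.64 in replicate 1, while that of the macrophage list was 1.26 and 6.03. In ABT replicate 4 they were 4.23 and 3.52. GDT replicate 4 was outside the set by CYBB alone (9.29 against at most 7.95 CPM in ABT); its macrophage mean was 3.02 and its NK-type median difference 0.766, and over GDT replicates 2 to 4 the median was 0.943. So NK-type receptors did not follow macrophage transcripts in each library. In GDT replicate 2 the list's median showed no rise, although some of its called genes were higher. KLRB1, KLRG1 and CD300A stood there at 116.1, 29.72 and 21.08 CPM, against at most 49.74, 18.97 and 19.46 in ABT. FCGR3A, also called, lay below ABT replicate 5. These called genes are 4 of the 21 members and were picked from the same libraries. Macrophages as a partial source therefore cannot be told apart from a difference in the T cells. In GDT replicates 2 and 3 the 172 genes called higher had a median difference of 1.36, against 1.48 in all 5, although the genes were picked from these libraries. NK cells as a source stay open, because FCER1G, a gene of NK and myeloid cells, differed by 0.12 with a 95% interval from -1.50 to 1.74. They stay open for the cytotoxic list as well, which was lowest among the GDT libraries where the NK cell markers were lowest, in replicate 2 (7.66 and 3.01, log2). A difference between the 2 cell types stays open too.

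The first principal component parted ABT replicates 1 to 3 from 4 and 5; in GDT, replicates 1 and 3 lay at -19.4 and -12.1, and replicate 2, at 24.1, lay on the side of 4 and 5. Its gene loadings had a Spearman correlation across genes of 0.159 with GC content and 0.0864 with transcript length, under the bound of 0.2, which argues against either as the main cause (86.7% of tested genes had a value; genes are not independent replicates). Depth does not account for ABT replicate 4, whose 28600000 reads lay within the 26800000 to 29700000 of ABT replicates 1 to 3 while its gap to the nearest of them was 2.29 times their range. For GDT replicate 4 the gap was 0.149 times the range, too small to decide. For donor 5 itself depth stays open: the loadings with and without both its libraries correlated at 0.668 across genes, short of the bound of 0.7. That comparison is limited, because without donor 5 the first component parted the groups instead (ABT at most -22.9, GDT at least 24.7). Cell cycle genes had the most negative median loading of the 31 lists and averaged 7.46 (log2) in donors 1 to 3 and 5.96 in donors 4 and 5. That parting held in ABT (7.70 to 7.78 in replicates 1 to 3, 6.18 and 6.04 in 4 and 5) but not throughout GDT. There, replicates 1 and 3 had 7.77 and 7.29, while replicate 2, at 6.46, lay below the 6.54 of replicate 4 (replicate 5 had 5.10). The groups also differed along the first component: GDT lay to the right of ABT in 5 of 5 same-numbered pairs, by 26.5 to 58.7. The labels give no group that parts donors 1 to 3 from 4 and 5, so no biological explanation was tested for that parting.

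Of 100 splits of the 10 libraries into 5 and 5, drawn from 126, 2 gave as many called genes, the real one included (376 genes, highest other 3683). For genes called at least 2-fold, 2 gave as many (313, highest other 910). Chance was thus excluded for the gene counts as a whole at the 0.05 level only if the libraries are taken as unpaired. These counts hold 15 receptor or immunoglobulin segments called higher and 62 called lower, and receptor genes define the 2 cell types. The splits were not run without them, so they do not exclude chance for the other genes. The split with 3683 genes set ABT replicates 1 to 3 with GDT replicates 1 and 3, the low end of the first component, and points to a structure of the samples. Of all 16 splits that part the 5 same-numbered pairs, the real one gave the most genes and the highest other 0, but the smallest share these 16 can give is 0.0625, so with the pairing kept the 0.05 level cannot be reached. For the number of lists, 25 of 100 splits gave 12 or more (highest other 18), so chance was not excluded.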

How the results depend on the processing

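The alternatives on donors 1 to 3, on donor 5 and with the replicate block in 2 list tests were chosen after seeing the data. Main counts were 172 genes higher and 204 lower, 139 and 174 of them at least 2-fold. They were 71, 113, 59 and 87 with no filter on low values, where more genes were tested. With a mean of at least 5 CPM, 99 were lower and 81 lower by 2-fold, and 57.0% of calls were higher, against 45.7%. A pseudocount of 5, which shrinks differences, gave 92 and 88 by 2-fold. The replicate block gave 334 higher and 382 lower, and sample weights 281 higher. The exact Wilcoxon test called 0 in each direction, since its smallest p of 0.00794, reached by 707 of 15499 genes, adjusts to 0.174; 1696 genes had an unadjusted p under 0.05, against 2331 by limma. Without donor 5 in both groups 103 were higher, 88 lower and 84 lower by 2-fold. With donors 1 to 3 only the counts were 48, 28, 48 and 27, with fewer samples. A term for donors 1 to 3 against 4 and 5 gave 346 and 351, which held all 376 main calls. Leaving out each library in turn gave 66 to 157 higher, 84 to 205 lower, 62 to 138 higher and 81 to 186 lower by 2-fold, and 6 to 20 lists. The lowest gene counts came without ABT replicate 3; the fewest lists came without GDT replicate 4 or 5 (6 each), the most without GDT replicate 2 (20) and ABT replicate 4 (19). Of the lists 12 passed; 0 did with the correlation estimated per list, 3 by fry (cytotoxic, naive and memory, and CD4 and CD8 lineage), 0 with the replicate block and the estimated correlation, and 2 with the replicate block and fry (the cytotoxic list was lost). Without donor 5 in both groups the calls of the CD3 (adjusted p = 0.117), regulatory (0.178), NK cell (0.0537) and macrophage (0.0950) lists were lost and the MAIT list passed (0.00513). With donors 1 to 3 only, the type 1 cytokine and ribosomal (0.0557 each), regulatory (0.0795) and NK cell (0.0807) lists were lost, the glycolysis (0.0148) and MAIT (0.000666) lists passed, and the macrophage and type 17 lists had too few measured members. With the term for donors 1 to 3, the type 1 cytokine list was lost (0.0760) and the glycolysis (0.0242) and fatty acid (0.0406) lists passed. Where no construction is named, the cause was not tested.

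Of the 55 called genes in the text, 0 changed sign under the alternatives run on single genes. All 55 calls held with a pseudocount of 0.1, median-of-ratios factors and the replicate block, 53 with a pseudocount of 5 and 52 under quantile normalisation; 23 of the 48 still tested were lost with donors 1 to 3 only. Leaving out 1 library lost 13 of the 55 in at least 1 fit, with adjusted p up to 0.13. Of the 68 genes tested and not called, 14 changed sign somewhere. With a pseudocount of 0.1 FCER1G was at -0.056, and without donor 5 in both groups at -0.33. Under quantile normalisation ITGB7 was at -0.045 and MT-CO1 at 0. With donors 1 to 3 only, ZAP70 was at 0.11, CD74 at -0.17, SREBF2 at -0.11, MT-CO1 at -0.18 and FCER1G at -0.025. Over the fits without 1 library the differences ran from -0.47 to 0.10 for PKM, -0.23 to 0.076 for RPL3, -0.38 to 0.21 for HLA-DRA, -0.72 to 0.011 for INSIG1, -0.16 to 0.048 for ZAP70, -0.16 to 0.47 for TIGIT, -0.19 to 0.13 for MT-CO1, -0.013 to 0.41 for SREBF2, -0.084 to 0.44 for DPP4, -0.028 to 0.38 for TNFRSF1B, -0.040 to 0.66 for CD74, -0.43 to 0.76 for FCER1G and -0.47 to 0.12 for MKI67. C1QA and CD14, below the filter, were not tested. The replicate block changed no call of a text gene by limma or of a list by camera or fry other than those given beside the results. Rescaling each library to the same total moved the median of all genes to -0.067 (log2), from -0.014. Low genes are limited most by depth in the 8 libraries of at most 31800000 reads.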

Other observations

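No test below was planned as such: the counts by receptor segment and the levels in the reverse direction were chosen after the results had been seen. Of 36 measured TRAV segments 34 fell in GDT and none rose, and of 33 TRBV segments 26 fell and none rose by limma. Summed over the 54 and 61 such segments in the table, TRAV stood at 282 ± 90.0 CPM in ABT and 26.0 ± 17.7 in GDT and TRBV at 290 ± 106 and 35.7 ± 23.1 (SD, n = 5 each). These sums took in V pseudogenes and TRAV segments with DV in their name, which the sum of 88 segments above left out. None of 14 TRBJ segments passed (2 higher at an unadjusted p under 0.05), and they summed to 47.8 ± 14 CPM in ABT and 56.6 ± 22.9 in GDT. Of 11 TRGV segments, all 11 higher at an unadjusted limma p under 0.05, 4 rose: TRGV9, TRGV4, TRGV7 and TRGV8. The last 3 were chosen after their values were seen and stood at 17.1 ± 4.29, 15.9 ± 3.72 and 11.9 ± 2.18 CPM in GDT and 5.53 ± 2.43, 2.82 ± 1.87 and 2.11 ± 1.07 in ABT. The TRGV segments other than TRGV9 resemble each other, so how reads divide among them is uncertain. The 3 measured TRDJ segments and the 1 measured TRGJ segment rose.

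In the reverse direction, TRDC in ABT stood at 1.48% ± 0.492 of the GDT mean, TRDV2 at 0.862% ± 0.433 and TRGV9 at 2.75% ± 1.37.

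Of the 3 lists with fewer than 5 measured members, which had no list test, no gene passed by limma among 4 dendritic cell, 4 granulocyte and mast cell and 3 platelet and erythroid markers (1 lower, 2 higher and 0 at an unadjusted p under 0.05). Of the granulocyte and mast cell markers 2 rose when adjusted over the list alone. LAMP3 and IL3RA, dendritic cell markers, were at 41.5 ± 32.4 and 19.5 ± 11.4 CPM in ABT and 9.73 ± 9.44 and 10.4 ± 6.59 in GDT (adjusted p = 0.316 and 0.388), and GP1BA, a platelet marker, was at 11.2 ± 3.11 and 9.40 ± 3.40 (adjusted p = 0.731).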
